A study of Sus scrofa with 6 samples.

How the data were processed

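Gene expression was measured in 6 clones of pig (Sus scrofa) keratinocytes, 3 grown from cornea and 3 from conjunctiva. Per the labels' protocols, biopsies of conjunctiva or of cornea lying 6 mm from the limbus came from domestic pigs. The labels name 2 animals and do not say which clone came from which. Keratinocytes were grown on irradiated 3T3-J2 cells, a mouse fibroblast line used as a feeder layer, and single cells were picked to found each clone. Total RNA was amplified in 1 cycle, labelled with biotin and hybridised to Affymetrix porcine arrays, 1 array per clone. The array run files also carry a project field that names an irradiation time course, which the labels do not mention. The groups used here follow the labels.

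The deposited table held log2 values that the authors had made with the robust multi-array average (RMA), per the submitters' processing notes. RMA subtracts background, quantile-normalises probe signals across arrays and fits 1 value per probe set. Its version, and which arrays were normalised together, were not given in the sources used here. Quantile normalisation gives all arrays nearly the same distribution, so a change in total RNA per cell cannot be seen in these values. The array medians lay between 4.4 and 4.478. For arrays, the number of arrays limits the precision. The 124 control probe sets were left out and 23999 were tested, without a filter on low values.

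Gene symbols came from the array's annotation table. Of the tested probe sets, 10069 had 1 symbol, 198 had several and 13732 were not named in the table. No gene was named from a probe set with several symbols. Gene IDs of 9989 single-symbol probe sets matched a RefSeq gene table of assembly Sscrofa11.1, which changed 0 symbols. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, which gave 6765 genes. No genome build was tied to the probe sets, so no coordinates are given.

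The comparison of conjunctiva with cornea used limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options), conjunctiva minus cornea, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p 0.05. Gene lists were tested with camera at its preset correlation of 0.01 over the lists with at least 5 measured genes, with adjustment over the 24 lists tested. Camera with an estimated correlation and the rotation test fry (statmod 1.5.0) were the alternatives. The similarity of clones was described by Pearson correlations across probe sets, which are not independent replicates, and by principal components. The design, the 25 gene lists, the rule for named genes and the alternatives other than those named as added were fixed before the data were examined.

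The named genes were up to 12 per direction, taken first from those past the threshold without overlap between the tissues and then by the smallest p. Added to these were up to 4 members of each list by the smallest p and 16 fixed marker genes. Of the 16, 4 had a probe set named by that gene alone. The other 12, KRT3, KRT12, PAX6, KRT4, KRT13, KRT7, MUC5AC, TP63, KRT14, KRT5, KRT15 and ALDH3A1, were not analysed here. From the members chosen by list, the text gives 1 to 4 for most lists. Where leaving out 1 clone moved a named difference by over 1.5 times, the fit that weakened it most is given beside it. A gene that the rule takes by p among those lower in conjunctiva is not reported here.

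The labels number the clones 1 to 3 in each tissue without saying what a shared number means. Deviations from the tissue means correlated between same-numbered clones (r = 0.354, 0.169 and 0.349 across probe sets for numbers 1, 2 and 3). The mean of these, 0.29, was the highest of the 6 possible pairings. Chance alone would put this pairing highest in 1 of 6 cases. In 6 of 6 clones the best correlation was with the clone of their own number in the other tissue. Deviations from a mean of 3 clones are not independent, so these 6 matches are not separate evidence. The clone number was therefore also fitted as a block. The labels do not state that the clones came from separate cultures. With the 2 animals that they name, the 3 clones of a tissue cannot all come from separate animals. The p-values therefore measure only the spread between these samples.

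All arrays were scanned on 1 day. Of the 2 fluidics stations, station 1 held cornea 1, conjunctiva 2 and conjunctiva 3, and station 2 held the others. Each of the 4 fluidics module numbers held arrays of 1 tissue only. The station was tested as a block and within each station, and the module number as a random block, which cannot part the module from the tissue. The module and the within-station fits, the latter with 1 array of 1 tissue in each station, the similarity without same-numbered pairs, the shares along splits that part these pairs and the estimated correlation joined to other alternatives were added after the data had been seen. Other alternatives were filters at the median and the 25th percentile of the mean, quantile normalisation again, array median centring, array weights, trend and robust options, leaving out ambiguous probe sets, 1 probe set per gene, a fold threshold, an unmoderated test and leaving out each clone in turn.

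The scripts were tested on simulated data with the spread of these arrays, in which the clones varied independently of each other. With 200 of 23999 probe sets changed in each of 20 simulations, limma called 73.2% of 2-fold, 96.2% of 4-fold and 98.5% of 8-fold differences, and 6.52% of its calls were false. For lists, camera called 0.521% of unchanged lists and 100% of simulations in which 1 list was moved by 1 on the log2 scale. When members of unchanged lists were given a shared correlation of 0.4, the preset correlation called 31.9% of them and the estimated correlation 0.104%.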

Results

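The expression profiles of 3 keratinocyte clones from the central cornea and 3 from the conjunctiva of the pig were compared on porcine arrays, as log2 RMA values of 23999 probe sets. The cornea and the conjunctiva are the neighbouring surface epithelia of the eye, and each clone descended from 1 cell grown on mouse feeder cells. The comparison asks which genes differ between clones of the 2 tissues. The 3' minus 5' signal of the control probe sets, a measure of RNA quality, overlapped between the groups for actin (0.77 ± 0.31 in cornea and 0.86 ± 0.28 in conjunctiva, log2, SD, n = 3), and for GAPDH (0.46 ± 0.19 and 0.70 ± 0.23).

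FOLR1, which encodes a folate receptor, was the named gene closest to the threshold, at 7.37 ± 0.21 in conjunctival and 4.83 ± 0.33 in corneal clones (log2, SD, n = 3), a 5.81-fold difference. SNRPN, an imprinted gene that encodes a component of small nuclear ribonucleoproteins, stood at 7.57 ± 0.18 in conjunctiva and 5.002 ± 0.64 in cornea, a 5.93-fold difference. In the other direction, the cysteine protease inhibitor CST6 was 5.79-fold lower in conjunctiva (7.29 ± 0.23 against 9.82 ± 1.18). None of these genes passed the threshold over all probe sets, and most of the genes measured differed little between the tissues.

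No probe set passed adjusted p 0.05 by limma. The count was 0 of 23999, with 648 at an unadjusted p under 0.05 (373 higher and 275 lower in conjunctiva, and 496 and 217 after array median centring), where an even spread of p-values would give 1200. The count was also 0 by the unmoderated test, and 0 with the clone number as a block, which brought the unadjusted count to 1204. Limma gave a smallest adjusted p of 0.0695, shared by FOLR1 (log2 difference 2.54, SE 0.20) and an unnamed probe set (difference -1.48, SE 0.10). FOLR1 passed when 1 probe set per gene was tested (limma adjusted p = 0.038), and both passed with limma's trend and robust options (adjusted p = 0.0252 for each). SNRPN was at an adjusted p of 0.569. The second FOLR1 probe set, at a low mean of 3.81, differed by 0.018.

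**Figure D1:**
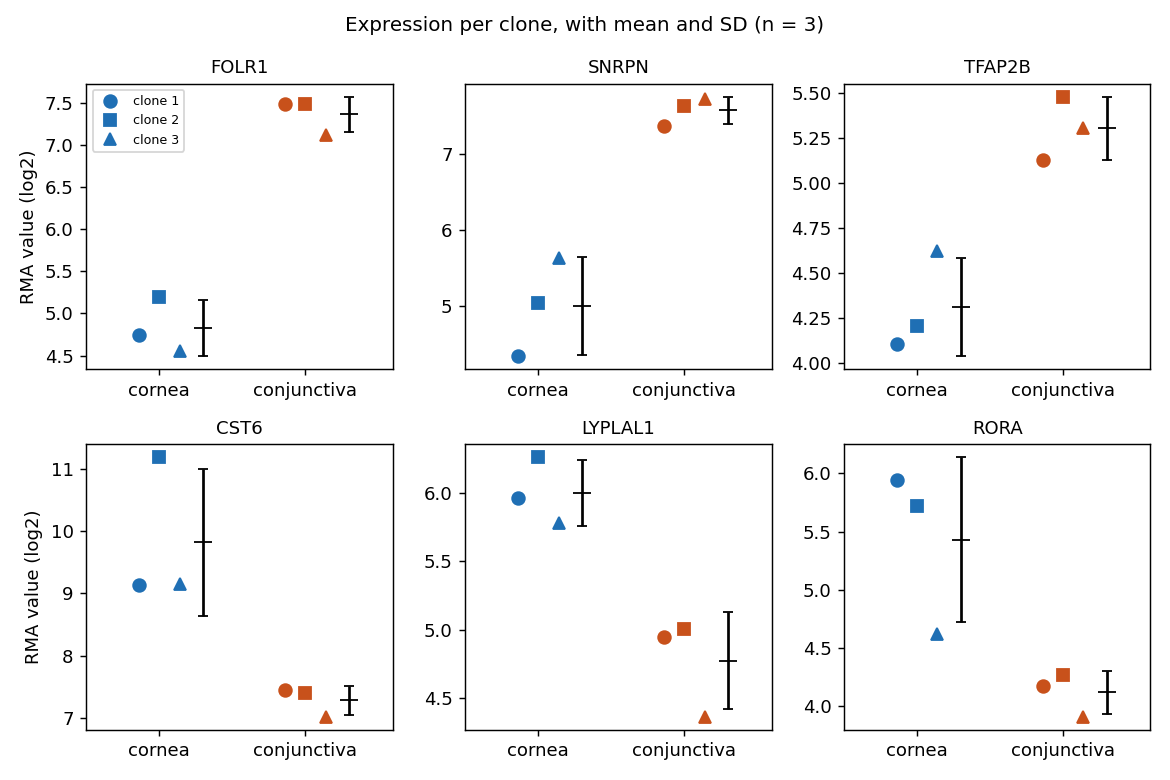
Log2 RMA values (y axis, a separate scale in each panel that does not start at 0) of 6 named genes in the 3 corneal and 3 conjunctival clones, with the mean and SD of each tissue (n = 3) in black and clone numbers as symbols. FOLR1 lies at 4.83 in cornea and 7.37 in conjunctiva on average and CST6 at 9.82 and 7.29, with no overlap between tissues in any of the 6 panels.

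The other genes named for the smallest p among those higher in conjunctiva did not pass either, each at an adjusted p of 0.9999 by limma. Among them the transcription factor TFAP2B was at 5.30 ± 0.17 in conjunctiva and 4.31 ± 0.27 in cornea (log2, SD, n = 3). The cyclin-dependent kinase inhibitor CDKN2D differed by 0.67 (SE 0.12), the cholesterol synthesis enzyme HSD17B7 by 0.51 (SE 0.10), DEPDC7 by 1.12 (SE 0.22) and the neuronal calcium sensor VSNL1 by 0.76 (SE 0.18). NUDT9, ZDHHC9, LOC100516665, the galactosyltransferase B4GALT4 and NUCB2 differed by 0.41 to 0.51. The second probe set of ZDHHC9 and both others of LOC100516665 had the opposite sign.

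The genes named for the smallest p among those lower in conjunctiva were likewise at adjusted p 0.9999 by limma. LYPLAL1 was at 4.77 ± 0.36 in conjunctiva and 6.00 ± 0.24 in cornea. The nuclear receptor RORA differed by -1.31 (SE 0.34), LOC100621607 by -1.65 (SE 0.43), the neuritin gene NRN1 by -1.17 (SE 0.30) and the orphan receptor GPR160 by -1.10 (SE 0.30). PHGDH, the enzyme that starts serine synthesis, differed by -0.72 (SE 0.21) and the aminopeptidase DNPEP by -0.62 (SE 0.18). CYGB, which encodes cytoglobin, the melanocortin receptor accessory protein MRAP and the monooxygenase FMO5 differed by -0.51, -0.44 and -0.37. The genes named by p in both directions were all without overlap between the 3 values of each tissue, as were 7.28% of all probe sets. Chance gives 10% for independent clones, and the other 3 splits that part all same-numbered clones gave 7.61%, 8.3% and 5.85%.

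Differences of at least 2-fold between tissue means were seen for 117 probe sets, 61 higher and 56 lower in conjunctiva, and differences of at least 4-fold for 17. The 95% confidence interval excluded a 2-fold difference for 91.9% of probe sets and a 4-fold difference for 98.8%. These shares include dim probe sets, since no filter on low values was used. Among probe sets with a mean at or above the median, the interval excluded a 2-fold difference for 85.9%. The fluidics station, as a block, left the limma count at 0 with 597 at an unadjusted p under 0.05, and within station 1 and station 2 alone it was 0 and 0, with 1435 and 748. Station 1 held 1 corneal and station 2 held 1 conjunctival array, so these last fits had 1 residual degree of freedom, assumed the lone array to vary like the others, and say nothing about stability.

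Cornification genes, which build the outer layer of stratified epithelia, and cell cycle genes were the lists that passed camera, 2 of the 24 tested. Of 11 measured cornification genes, 10 were lower and 1 higher in conjunctiva, with a median difference of -0.33 and a mean of -0.71 on the log2 scale (camera adjusted p = 0.00052, and adjusted p = 0.843 with an estimated correlation). Of 27 measured cell cycle genes, 23 were higher and 4 lower, with a median of 0.40 (camera adjusted p = 0.00749, and adjusted p = 0.843 with an estimated correlation). Neither list passed fry (adjusted p = 0.886 for both).

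No cornification gene passed over all probe sets, and 1 of the 11, CST6, passed when adjusted over the list alone (limma adjusted p = 0.0288). KRT1, a keratin of differentiating epidermal cells, was at 6.64 ± 2.24 in conjunctiva and 8.90 ± 2.09 in cornea, a difference of -2.25 (SE 1.37, and -1.18 without cornea 2). Its partner KRT10 was at 6.91 ± 0.03 and 7.17 ± 0.11, and the transcription factor KLF4 at 8.14 ± 0.54 and 8.78 ± 0.60, a difference of -0.65 that was -0.34 without conjunctiva 2. As a mean over the list, the corneal clones 1, 2 and 3 lay at 0.54, 0.95 and -0.43 from the mean of all 6, and the conjunctival clones at 0.40, -0.91 and -0.56. The call ended without conjunctiva 3 (median -0.23, camera adjusted p = 0.0705), and the median was -1.23 within station 1, where cornea 1 was the lone corneal array, and 0.06 within station 2, where conjunctiva 1 was the lone conjunctival array.

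No cell cycle gene passed, over all probe sets or when adjusted over the list alone. The cyclin gene CCNB2 was at 7.12 ± 0.28 in conjunctiva and 5.97 ± 1.24 in cornea, a difference of 1.15 that was 0.46 without cornea 2. NUSAP1, a spindle gene, and the mitotic kinase genes AURKA and AURKB differed by 0.41, 0.33 and 0.42, and by 0.19, 0.10 and 0.11 without cornea 2. The second AURKA probe set differed by -0.04. Cornea 2 stood apart from the rest, with a list mean of -1.01, while the other corneal clones lay at 0.09 and 0.41 and the conjunctival ones at 0.25, -0.03 and 0.29. Without cornea 2 the median turned to -0.11, and the call also ended without conjunctiva 1 (0.33, adjusted p = 0.0818) or conjunctiva 3 (0.31, adjusted p = 0.156) and with the station as a block (0.35, adjusted p = 0.103). Against the same lone arrays the median was 0.00168 within station 1 and 0.54 within station 2.

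**Figure D2:**
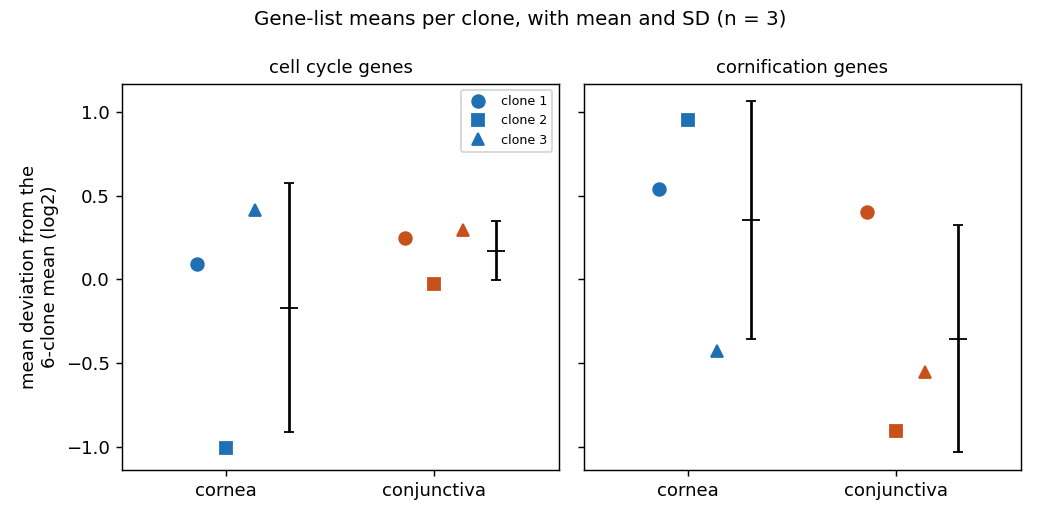
Mean over the cell cycle list (27 genes) and the cornification list (11 genes) in each clone, as the deviation from the mean of all 6 clones on the log2 scale (y axis), with the mean and SD of each tissue (n = 3) in black. Cornea 2 lies at -1.01 on the cell cycle list and at 0.95 on the cornification list, and the tissues overlap on both.

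The other 22 lists tested did not pass camera, with medians from -0.09 to 0.16 and adjusted p from 0.0869 to 0.843. In 3 lists 1 gene passed when adjusted over the list alone: CST6, HSD17B7 among cholesterol synthesis genes (limma adjusted p = 0.0193, with 9 of 12 measured genes lower in conjunctiva) and TFAP2B among epithelial transcription factors (0.0178, with 13 of 24 higher and NFIA at 0.45). In all other lists this count was 0.

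The lists of genes known from each of the tissues did not pass, but both were measured only in part. Of the corneal list 10 of 22 symbols were measured, and of the conjunctival and mucosal list 13 of 32. The markers KRT3, KRT12, PAX6, KRT4, KRT13 and MUC5AC had no probe set named by that gene alone and were not tested. Of 13 measured conjunctival and mucosal genes, 8 were higher and 5 lower in conjunctiva (median 0.12, camera adjusted p = 0.609). The membrane mucin gene MUC4 was low in all corneal clones (2.97 ± 0.05) and at 3.98 ± 1.14 in conjunctiva, where conjunctiva 2 reached 5.29 and without which the difference of 1.01 was 0.35. S100A9, a calcium-binding defence protein gene, differed by 1.74 (SE 1.05), and by 0.95 without cornea 3 and 2.93 without cornea 2. The simple-epithelium keratin KRT8 differed by -1.36 (SE 0.61), and by -0.77 without conjunctiva 1 and -2.07 without conjunctiva 2, and the water channel gene AQP5 by -0.69 (SE 0.44, and -0.14 without cornea 2). Of 10 measured corneal genes, 6 were higher and 4 lower in conjunctiva (median 0.05, adjusted p = 0.662). The transcription factor gene MEIS1 differed by 0.36 (0.19 without cornea 3), the proteoglycan gene DCN by 0.92 (SE 0.62, and 0.25 without conjunctiva 2), the gap junction gene GJA1 by -0.23 (-0.10 without conjunctiva 1) and ALDH1A1, which stood above 11 in both tissues, by 0.27 (-0.22 without cornea 3). The second DCN probe set had the opposite sign. The fixed genes KRT19, MUC1 and VIM differed by 0.43 (SE 1.07), 0.12 (SE 0.15) and 0.51 (SE 0.29), and by -0.34 and 0.03 without cornea 1 and 0.22 without conjunctiva 3, in this order. The other MUC1 probe set had the opposite sign.

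Among lists of cell behaviour, 15 of 27 innate defence genes were higher in conjunctiva (adjusted p = 0.609). The chemokine gene CXCL14 led them at 7.32 ± 0.78 against 5.19 ± 0.92, without overlap, and PTGS2, which encodes an inducible cyclooxygenase, was at 7.42 ± 1.92 against 9.28 ± 0.64, a difference of -1.86 that was -0.76 without conjunctiva 2. Of 22 interferon response genes 17 were higher (0.338), with IFI44L at 0.62 (SE 0.36, and 0.23 without conjunctiva 2) and the peptide transporter gene TAP1 at -0.27 (-0.18 without cornea 2). The mean of that list was 0.55 above the mean of all clones in conjunctiva 2 and lay between -0.16 and -0.03 in the other 5, and the list passed camera without conjunctiva 1 (adjusted p = 0.0293, and adjusted p = 0.838 with an estimated correlation). Basement membrane and adhesion genes split 10 to 9 (0.609), with the integrin gene ITGA5 at 0.49, whose other probe set had the opposite sign, and the hemidesmosome collagen gene COL17A1 at -1.20 (SE 0.70, and -0.38 without cornea 1). Stem and progenitor genes were higher for 3 of 13 (0.609), and ITGB1 was nearly equal at 11.70 ± 0.02 and 11.78 ± 0.02. Xenobiotic and antioxidant genes split 14 to 14 (0.581), with GCLC at -0.42, GSTM3 at -0.49 and MGST3 at 0.25. The median of that list, 0.000468, and its mean, -0.01, differed in sign, and so did 3 of the 4 other GCLC probe sets from the one named.

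Signalling and metabolic lists gave adjusted p from 0.478 to 0.843 by camera. Higher in conjunctiva were 4 of 7 Notch genes, with the ligand gene JAG1 at 0.66 (0.40 without cornea 3) and 1 of its 2 other probe sets of opposite sign, 13 of 18 TGF-beta and BMP genes, with ID4 at 0.21, 6 of 11 Wnt genes, 9 of 21 glycolysis and hypoxia genes, 9 of 21 oxidative phosphorylation genes and 10 of 23 stress genes, with HSPH1 at 0.27. In the cholesterol list MSMO1 differed by -0.20 (0.06 without cornea 1). The epithelial-mesenchymal list had a median of -0.03 with a mean of 0.04 (adjusted p = 0.765), and the glycolysis list a median of -0.03 with a mean of 0.000612.

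Markers of other cell types did not pass in the comparison of all 6 arrays without a block or recentring. Fibroblast and keratocyte markers came closest, with 16 of 23 lower in conjunctiva and a median of -0.07 (adjusted p = 0.0869), and passed with array median centring, with the station as a block, within station 2 and without conjunctiva 2, but in none of these fits with an estimated correlation (adjusted p = 0.889, 0.759, 0.965 and 0.822 in this order). Leukocyte and melanocyte markers passed within station 2 as well, but with an estimated correlation no list did (smallest adjusted p = 0.965). PRRX1 differed by -0.38 and COL5A1 by -0.57 (-0.21 and -0.24 without conjunctiva 1), with 3 of 5 other COL5A1 probe sets of the same sign. The leukocyte, endothelial and goblet lists had median levels of 3.71, 3.9 and 3.97, below the array medians of 4.4 to 4.478. The counts of higher and lower members in these 3 lists are therefore mostly of dim probe sets. Leukocyte markers were lower for 11 of 19 (0.581, TYROBP at -0.27 and -0.15 without cornea 3), endothelial markers for 8 of 11 (0.609, PECAM1 at 0.56), melanocyte markers for 8 of 9 (0.478, GPNMB at -0.73, 0.18 without conjunctiva 3, and 1 of its 4 other probe sets of opposite sign), goblet and secretory genes for 5 of 8 (0.581) and histocompatibility genes for 9 of 17 (0.581, SLA-DQA1 at -0.31 and -0.18 without cornea 3). Of the sex-linked list only SRY and EIF1AY were measured, at differences of 0.03 and -0.04 (-0.02 without conjunctiva 1 and 0.11 without conjunctiva 2), and the list was not tested.

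Clones of 1 tissue and of different tissues were about equally alike. Pearson correlations across probe sets averaged 0.9784 over the 6 pairs within a tissue (0.971 to 0.9817) and 0.9797 over the 9 pairs between tissues (0.9738 to 0.9869). Without the 3 same-numbered pairs, which deviate together, the between-tissue mean was 0.9777 over 6 pairs, which turned the sign of the difference. The closest pairs joined the tissues, cornea 3 with conjunctiva 3, at 285 probe sets at least 2-fold apart, and cornea 1 with conjunctiva 1, at 423. The farthest pair was within the cornea, clones 2 and 3, at 1018. The within-tissue mean minus the between-tissue mean was -0.00138, and 8 of the 10 splits of the clones gave a value as large in an exact permutation count, where the smallest p is 0.1. Without same-numbered pairs it was 0.000674, and 2 of the 4 splits that part all such pairs gave a value as large. Tissue took a median of 10.4% and a mean of 17.4% of a probe set's variance between clones. The mean is 20% with no tissue effect among independent clones, and it was 18%, 18% and 15.3% along the other 3 splits that part all same-numbered pairs. The first principal component held 34.6% of the variance and did not part the tissues, with means of 3.53 ± 35.7 in cornea and -3.53 ± 21.5 in conjunctiva (SD, n = 3).

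**Figure D3:**
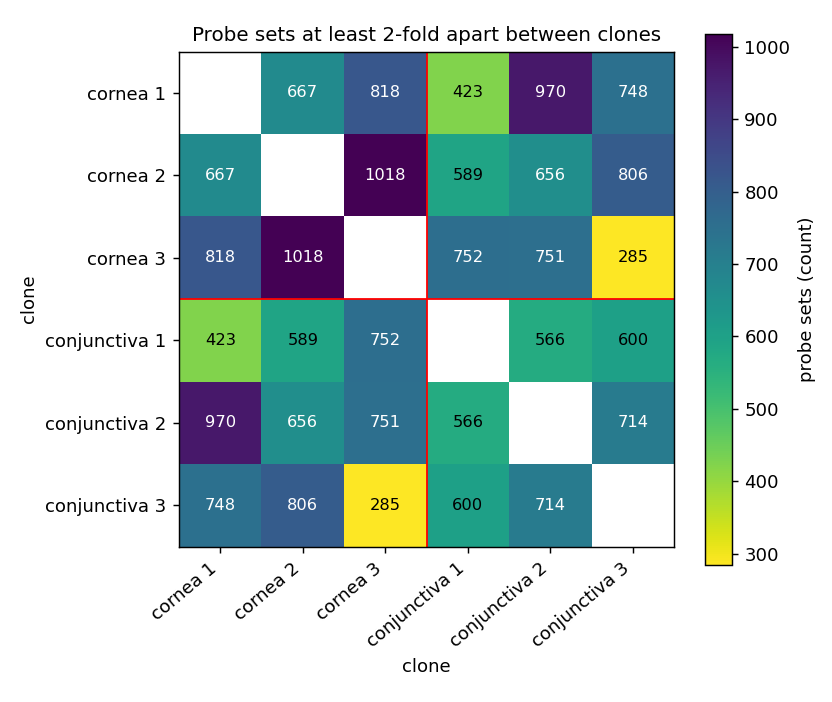
Number of probe sets at least 2-fold apart (colour and digits) for each pair of the 6 clones, with red lines between the tissues. Pairs range from 285, cornea 3 with conjunctiva 3, to 1018, cornea 2 with cornea 3.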

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

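The fits by fluidics module and within each station, the similarity without same-numbered pairs, the estimated correlation joined to other alternatives and the count at an unadjusted p were added after the data had been seen. The count of probe sets past the threshold was 0 in 19 of 23 alternatives. Of these, the added 2-fold threshold could only give 0 again. The fits within a station or without 1 clone had fewer arrays to make a call. The count was 0 in each fit without 1 clone (range 0 to 0), where the smallest adjusted p ran from 0.0642 to 0.709. With the module as a random block it was also 0 (0.0505). Each module number held arrays of 1 tissue only, and arrays that shared a number ran on different stations. That fit therefore cannot part the module from the tissue. The 4 exceptions were 2 with limma's trend and robust options, 1 with 1 probe set per gene, where fewer tests were adjusted for, 2 at a threshold of adjusted p 0.10 and 648 at an unadjusted p of 0.05. With the clone number as a replicate block the count was 0 (smallest adjusted p 0.108, 1204 at an unadjusted p under 0.05), and the same 2 lists passed, so the block changed no call. The count of lists past the threshold, 2, became 0 with an estimated correlation, 0 with fry, and 0 to 3 without 1 clone. It was 6 among the arrays of station 2, 2 among those of station 1 and 3 with array median centring. The within-station fits have a lone array in 1 arm. Lists that passed only in some fits were fibroblast markers, cholesterol genes (without conjunctiva 1 and within each station), interferon genes (without conjunctiva 1), oxidative phosphorylation genes (without cornea 2), and stem, leukocyte and melanocyte genes (within station 2). With the correlation estimated, 0 lists passed in these fits (smallest adjusted p 0.759, with the station as a block). The cell cycle median, 0.40, ran from -0.111 (without cornea 2) to 0.701 without 1 clone, and camera's direction turned within station 1 (0.00168). The cornification median, -0.33, ran from -0.767 to -0.209 without 1 clone and turned within station 2 (0.0593). The within-tissue minus between-tissue correlation, -0.00138, moved to -0.00573 over the 1000 most variable probe sets and -0.0788 with each probe set centred, ran from -0.00389 to 0.00146 without 1 clone, and turned to 0.000674 without same-numbered pairs. Of 384 differences of 64 named genes without 1 clone, 376 kept their sign, as did 27 of 27 taken as the mean of a gene's probe sets. A gene without overlap between the tissues cannot turn when 1 clone is left out. All genes named by p were of this kind, so their kept signs were fixed by the choice and show no stability. The clone number as a block leaves a difference as it is, and array median centring moved each by 0.02 to 0.03, so both say little about the sign. For 30 of the genes, none of them past the threshold, leaving out 1 clone moved the difference by over 1.5 times. The 8 differences that turned came from fits without 1 clone, in which MSMO1 ran from -0.354 to 0.0589, ALDH1A1 from -0.219 to 0.8, SRY from -0.0198 to 0.0497, GPNMB from -1.86 to 0.178, KRT19 from -0.34 to 1.35 and EIF1AY from -0.154 to 0.105. Where not named, the cause was not tested. Signal over background is not part of the values used, so dim probe sets were not set apart except by the filters on the mean, which left the count at 0.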

Other observations

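The tests of a structure that crosses the tissues, of the fluidics station by its split and of the second SNRPN probe set were chosen only after the results were seen, as were the genes named for their spread between clones or outside the fixed rule. The fits with an estimated correlation and with the station as a block were fixed before the data were examined, but were set against members that move together and against the station only afterwards. Single genes differed widely between clones of the same tissue. SST, the somatostatin gene, was at 10.05, 13.05 and 4.92 in corneal clones 1, 2 and 3 and at 9.62, 5.95 and 9.18 in conjunctival clones 1, 2 and 3, the largest SD around the tissue means of the 6765 genes. The matrix metalloprotease gene MMP7 was at 11.64 in conjunctiva 2 and at most 6.23 in the other 5 clones. ARG1, which encodes arginase, ranged from 3.28 in cornea 3 to 8.92 in conjunctiva 1, the matrix protein gene SPARC from 5.31 in cornea 3 to 11.02 in conjunctiva 2, and IVL, the involucrin gene of differentiating keratinocytes, from 7.22 in conjunctiva 2 to 11.4 in conjunctiva 1. KRT19 was at 10.36 in cornea 3 and 10.44 in conjunctiva 2 against 7.02 in cornea 1 and 7.15 in conjunctiva 1. In a permutation test against 10000 random lists matched on mean expression, the median SD between clones of the same tissue was higher than in nearly all random lists for cell cycle genes (0.60 against a random median of 0.26), cornification genes (0.68 against 0.23), innate defence genes (0.48 against 0.21) and conjunctival and mucosal genes (0.84 against 0.21), each at p = 1e-04, the smallest these draws can give, and an adjusted p of 6e-04. In all, 12 of 24 lists varied more than random lists at an adjusted p under 0.05, and the other 8 were epithelial-mesenchymal (0.0014), corneal (0.004), basement membrane (0.0048), interferon (0.0048), epithelial transcription factor (0.0059), stress (0.0084), stem and progenitor (0.014) and fibroblast genes (0.027). Oxidative phosphorylation genes (0.19, percentile 8.41), Wnt genes (0.15, percentile 12.16) and goblet genes (0.14, percentile 14.77) varied no more than random lists. Genes of a list are not independent, so these percentiles describe these 6 clones. The spread of a list may rest mostly on 1 clone. The cell cycle list mean was -1.01 in cornea 2, with an SD of 0.748 in cornea and 0.175 in conjunctiva. The interferon list mean was 0.545 in conjunctiva 2 and between -0.161 and -0.0311 in the other clones. The cornification list mean varied in both tissues, with an SD of 0.709 in cornea and 0.678 in conjunctiva.

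Several genes outside the fixed rule also differed without overlap. ZFP42, a pluripotency-associated zinc finger gene, was at 4.95 ± 1.55 in conjunctiva and 7.63 ± 0.74 in cornea (log2, SD, n = 3), and GLRX, the glutaredoxin gene, at 5.17 ± 0.78 and 7.51 ± 1.28, with its second probe set also lower. PTHLH, a parathyroid hormone-related peptide gene, was at 10.08 ± 0.23 in conjunctiva and 7.997 ± 1.59 in cornea, and the retinoic acid-binding protein gene CRABP2 at 11.08 ± 1.06 and 9.49 ± 0.14. None passed limma's threshold. With no overlap and at least a 2-fold difference there were 40 probe sets, 21 higher and 19 lower in conjunctiva.

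No probe set passed between the tissues. The clones allow 10 splits into 3 against 3, too few for a share under 0.05: the real split gave 0 and the highest other gave 13, while at an unadjusted p under 0.05 the real split gave 648, as many or more were given by 9 of 10, and the highest other gave 2284. A lack of power is not decided. In simulated data with this spread and 200 changed probe sets, limma called 96.2% of 4-fold and 98.5% of 8-fold differences. The simulated probe sets varied independently of each other, and so did the simulated clones. On the arrays same-numbered clones deviated together (mean r = 0.29). The 200 planted changes also make the adjusted threshold easier to reach than few changes would. On the arrays, none of the 17 probe sets with at least a 4-fold difference of means passed. The simulation therefore cannot exclude that 3 clones per tissue were too few. A structure of the clones that crosses the tissues remains a candidate explanation. Between cornea 1, cornea 2 and conjunctiva 1 and the remaining clones 9 probe sets were on or off, against 2 between the tissues. The same split gave the 13 calls, although the highest of 9 other splits was picked for this. That split parts 1 of the 3 same-numbered pairs and the tissue split all 3, so these counts are unlike. The other splits that part all 3 pairs gave 0 on or off probe sets. Probe sets that set 1 clone apart numbered 55 (cornea 1), 54 (cornea 2), 51 (conjunctiva 2), 21 (cornea 3), 12 (conjunctiva 3) and 8 (conjunctiva 1). The fluidics station stays open, since its split gave 354 at an unadjusted p under 0.05, the fewest of the 10 splits but too few splits to decide, and the tissue count was 0 with the station as a block, as do the animal of origin and a true likeness of the tissues in culture, which were not tested.

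A probe set counted as on or off where the largest gap between neighbouring values of the 6 clones was over 1 on the log2 scale. That gap also had to be over 3 times the next largest gap. The 9 included GSTA1, a glutathione transferase gene, at 8.02, 7.99 and 8.64 in cornea 1, cornea 2 and conjunctiva 1 and at 3.56, 3.39 and 3.37 in cornea 3, conjunctiva 2 and conjunctiva 3. In the same order an unnamed probe set was at 3.29, 3.11 and 3.38 and at 10.5, 9.68 and 10.3. PTBP3, VDAC2 and LOC100152209 were also among them, with gaps of 1.51, 1.43 and 1.38. Of the 4 splits that part all 3 same-numbered pairs, the real one gave 1204 probe sets at an unadjusted p under 0.05 with the clone number as a block, and the others gave 1479, 1240 and 563, the last following the station. None of the 4 gave a probe set past adjusted p 0.05 with the block by limma.

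Cell cycle genes were higher and cornification genes lower in conjunctival clones by camera at its preset correlation, but with an estimated correlation the smallest adjusted p was 0.843. Of the 10 splits, again too few for a share under 0.05, 9 gave as many lists as the real 2, the highest other gave 6, and the split by station gave 4, while the station as a block left 2, the cornification and the fibroblast lists. Members that move together between clones may have made both calls. Their estimated correlation was 0.81 for cell cycle and 0.39 for cornification genes, against the preset 0.01, and with it neither call was made. With an estimated correlation, though, 0 lists passed in any of the 10 splits. The loss of both calls therefore cannot tell such members from a true shift. The cell cycle shift may rest on 1 clone, since its median turned to -0.111 without cornea 2. The cornification median kept its sign without any 1 clone, at -0.209 in the fit that weakened it most. The cornification call ended without conjunctiva 3 (camera adjusted p = 0.0705). The mean over the cornification list was 0.539, 0.953 and 0.401 in cornea 1, cornea 2 and conjunctiva 1. In cornea 3, conjunctiva 2 and conjunctiva 3 it was -0.429, -0.909 and -0.556. The list mean thus parted along the split that crosses the tissues and overlapped between the tissues. A difference in growth or differentiation between the tissues stays open and was not tested.

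SNRPN was higher in conjunctival clones by 2.57 on the log2 scale, without passing limma's threshold (adjusted p = 0.569). A faulty probe set is argued against, since the gene's other probe set differed by 1.35 in the same direction, also without overlap. A shift of imprinted genes as a class stays open: the 24 other imprinted genes measured gave p = 0.298 in a rotation test of either direction, a smooth form of a permutation test, but that test called none of the 24 lists either (smallest p = 0.0873), so the bound set on this p before it was seen could exclude nothing. Of the 24 genes, TFPI2 (1.42) and GRB10 (0.372) were also higher and NAP1L5 (-0.122) lower without overlap, and the median difference was 0.0291. Of all probe sets 7.28% were without overlap, and chance gives 10% for independent clones. NAP1L5 was dim and barely parted, with cornea 3 and conjunctiva 2 both at 3.66 after rounding. A change at the SNRPN locus in the animals or founder cells of the clones, and a difference between the tissues, stay open and were not tested.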
